A study of Mus musculus with 4 samples.

How the data were processed

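RNA sequencing of mouse splenic CD4+ T cells was deposited as a table of 34745 genes with values for 4 libraries: naive cells, and Th0, Th17 and Treg cells collected after 3 days of culture. The cytokines of the Th17 and Treg conditions are not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol, and libraries were built and sequenced at a sequencing institute on an Illumina HiSeq platform. The submitters' processing notes name Bowtie2, RSEM and the mouse builds GRCm38.p6 and mm10, without versions or roles. Strandedness, read length and the gene annotation are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. The authors deposited whole-number read counts per gene, with no normalization, and if they came from RSEM estimates these had been rounded. Per the file headers the table also holds FPKM values by the authors. These equalled the count divided by gene length and by the library's table total, with the same length in all 4 libraries for 8988 of 8988 genes with at least 50 counts in all of them (tolerance 0.1%). Of the gene identifiers, 34344 (98.8%) were found in the GENCODE vM21 annotation of GRCm38, and 34323 of those overlapped its coordinates. In 15007 genes no library had a count, and 59 symbols stood on more than 1 identifier.

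The groups came from the cell type given in the labels. With 1 library per group no test between conditions was possible, so no p-value, SD or count of significant genes was computed. Counts were scaled with TMM normalization factors (edgeR 4.0.16 in R 4.3.3), which were 1.03 for naive, 0.850 for Th0, 1.06 for Th17 and 1.08 for Treg. For each of 4 comparisons, genes with at least 10 counts in at least 1 of the 2 libraries were tested for size. The log2 ratio was taken on CPM with a pseudocount of 1, which understates the ratio of low genes. A gene was called when that ratio was at least 2-fold and the 95% exact conditional (Clopper-Pearson) interval of the count ratio excluded 1. Such an interval compares the reads of a pair of libraries and covers counting error only, since the reads carry no molecular identifiers. Folds were computed without the pseudocount. Where a count was 0 the fold was taken against 3 counts and is a bound. Intervals of single levels were exact Poisson intervals.

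The depth set the floor: 1 count was worth 0.0817 CPM in naive, 0.114 in Th0, 0.0762 in Th17 and 0.0902 in Treg, and 3 counts 0.245, 0.343, 0.229 and 0.271 CPM. Before the data were examined, 33 gene lists and the rule for named genes were fixed. The rule named the 12 highest and 12 lowest log2 ratios among genes with at least 10 CPM in 1 of the 2 libraries. It left out predicted genes, clone names, receptor segments, pseudogene names and mitochondrial genes. It also named up to 4 members with the largest ratios of each list that stood apart or that the comparison was about, the H3K36 methyltransferases and lysophospholipid acyltransferases, and a set of lineage genes as a check of the labels. Heat shock genes in the closing part, and a few list members given beside a count, were chosen after their values were seen. Some genes that the rule named are not reported here. A list with at least 3 tested members stood apart when its median log2 ratio lay outside the central 95% of 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression. This describes these libraries and is not a test. Across the 4 comparisons 46 of 125 lists stood apart, and 6.25 would if genes varied independently. Members of a list may vary together, lists share members and the comparisons share libraries, so the excess cannot be judged from these numbers. Of the listed symbols, Riox1 was not in the table.

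The calls were tested on simulated data, with Poisson counts drawn from the real means and library sizes and 200 genes changed. The changed genes were picked among those with a mean of at least 10 CPM. The simulated counts held counting error only, with the library sizes known, so they do not give the error rate of the real calls. For Th0 over naive, 13552 simulated genes were tested, all 3-fold and 6-fold changed genes were recovered, and 4 unchanged genes were called. For Th17 over Th0, Treg over Th0 and Th17 over Treg, with 12930, 12749 and 13265 simulated genes tested, 2, 5 and 1 unchanged genes were called. A gene was noted as having a near-identical copy when a transcript of another gene aligned to it over at least 300 nt at 95% identity or more (minimap2). Alternatives to the scaling, pseudocount, count filter, unit and depth were run, including DESeq2 1.42.0 size factors, library totals, upper quartile scaling and the authors' FPKM. The other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.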

Results

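RNA was sequenced from 4 libraries of CD4+ T cells of wild-type C57BL/6 mice, with 1 library in each group. The naive library came from CD4+ T cells taken directly from the spleen. Th0 cells had been stimulated through CD3 and CD28 for 3 days. Th17 and Treg cells were collected after 3 days under their differentiation conditions, whose cytokines the labels do not give. The total count was 11901949 in naive, 10272122 in Th0, 12414372 in Th17 and 10256627 in Treg, and 13526, 11686, 13043 and 12799 genes had at least 10 counts. Because each group had 1 library, no difference reported here has a replicate check, and every interval is a 95% counting interval that covers counting error only. Folds are ratios of CPM, the read count scaled by the effective library size, and log2 ratios were taken after adding 1 CPM. A gene was called higher or lower when it differed at least 2-fold on that scale and its counting interval excluded equality. Scaling to library totals in place of TMM moved the median log2 ratio of all tested genes by -0.24 for Th0 over naive, 0.28 for Th17 over Th0 and 0.31 for Treg over Th0. Upper quartile scaling moved it by -0.12, 0.13 and 0.14.

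The genes that define the lineages were read in every library as a check of the labels. Il17a and Il17f, which encode the cytokines that define Th17 cells, stood at 90.4 and 118 CPM in Th17, 14.7 and 39.9 CPM in Treg, and at most 0.458 CPM in Th0 and naive. Foxp3, which encodes the transcription factor of regulatory T cells, had 129 CPM in naive, 51.5 in Treg, 11.3 in Th17 and 1.37 in Th0. Among the genes of other helper lineages, Tbx21 had 67.8 CPM and Gata3 127 CPM in Th0, against 23.5 and 57.5 in naive, 6.10 and 33.8 in Th17 and 9.02 and 58.7 in Treg. Ifng had 9.88 CPM in naive, 7.33 in Th0, 6.25 in Th17 and 11 in Treg, and Il4 lay between 0.721 and 3.55 CPM in the 4 libraries.

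**Figure D1:**
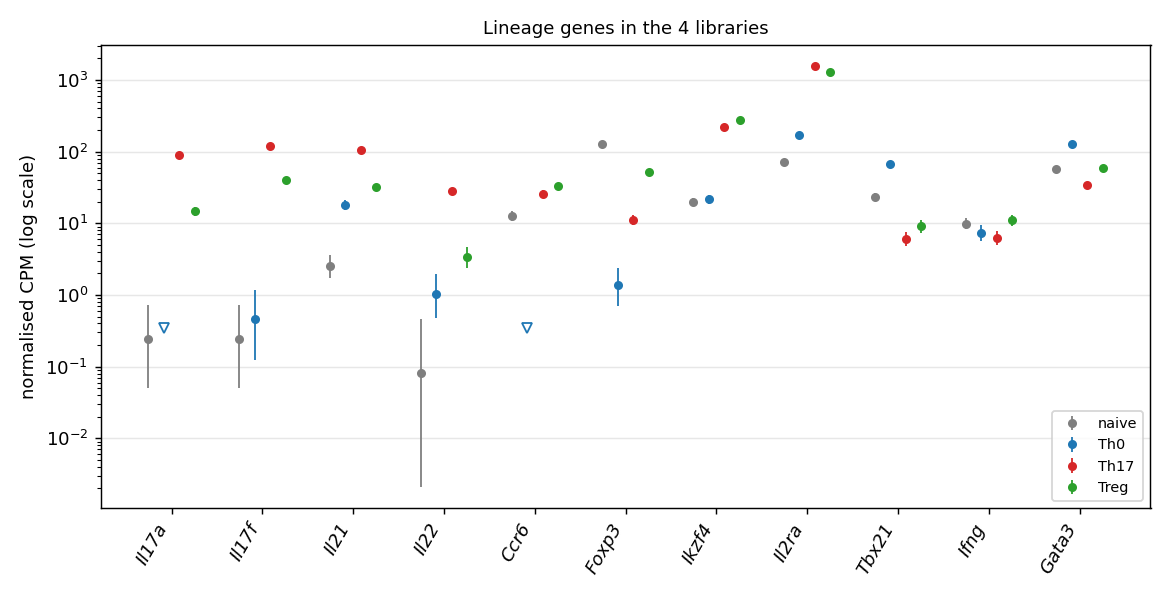
Normalised CPM of lineage genes on a log scale, with the gene on the horizontal axis and 1 point per library. Bars are 95% Poisson intervals of the count (counting error only), and open triangles mark a count of 0 drawn at the level of 3 counts. Il17a stood at 90.4 CPM in Th17 and 14.7 CPM in Treg, and Foxp3 at 129 CPM in naive and 51.5 CPM in Treg.

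The series concerns Setd2, which trimethylates histone H3 at lysine 36, and Lpcat4, a lysophospholipid acyltransferase. Setd2 (chromosome 9, 110532597 to 110618633, GRCm38) had 246 CPM in naive, 341 in Th0, 149.6 in Th17 and 133 in Treg. It was 2.28-fold lower in Th17 and 2.56-fold lower in Treg than in Th0, and the Th17 call was met under 3 of 4 scalings. Both ratios rest on the same Th0 library, so they cannot be assigned to the Th17 or Treg conditions. The naive level lay between that of Th0 and those of Th17 and Treg. Lpcat4 (chromosome 2, 112239468 to 112247111) had 49.6 CPM in naive, 60.6 in Th0, 44.0 in Th17 and 41.7 in Treg, and it met the 2-fold rule in none of the 4 comparisons. Its log2 ratio was -0.45 for Th17 over Th0 (interval -0.63 to -0.29) and 0.08 for Th17 over Treg (interval -0.10 to 0.26). Of the other H3K36 methyltransferases, Whsc1 (Nsd2) had 53.0, 389, 138 and 165 CPM in naive, Th0, Th17 and Treg, and Whsc1l1 had 309, 802, 506 and 471 CPM. Nsd1 had 340.1, 183, 313 and 296 CPM in the same order, Ash1l 226, 154, 143 and 125 CPM, Smyd2 9.06, 6.98, 39.6 and 33.0 CPM, and Setmar 4.17, 0.687, 4.27 and 3.16 CPM. Agpat3 had the highest level among the acyltransferases in every library, with 172 CPM in naive, 196 in Th0, 342 in Th17 and 306 in Treg.

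**Figure D2:**
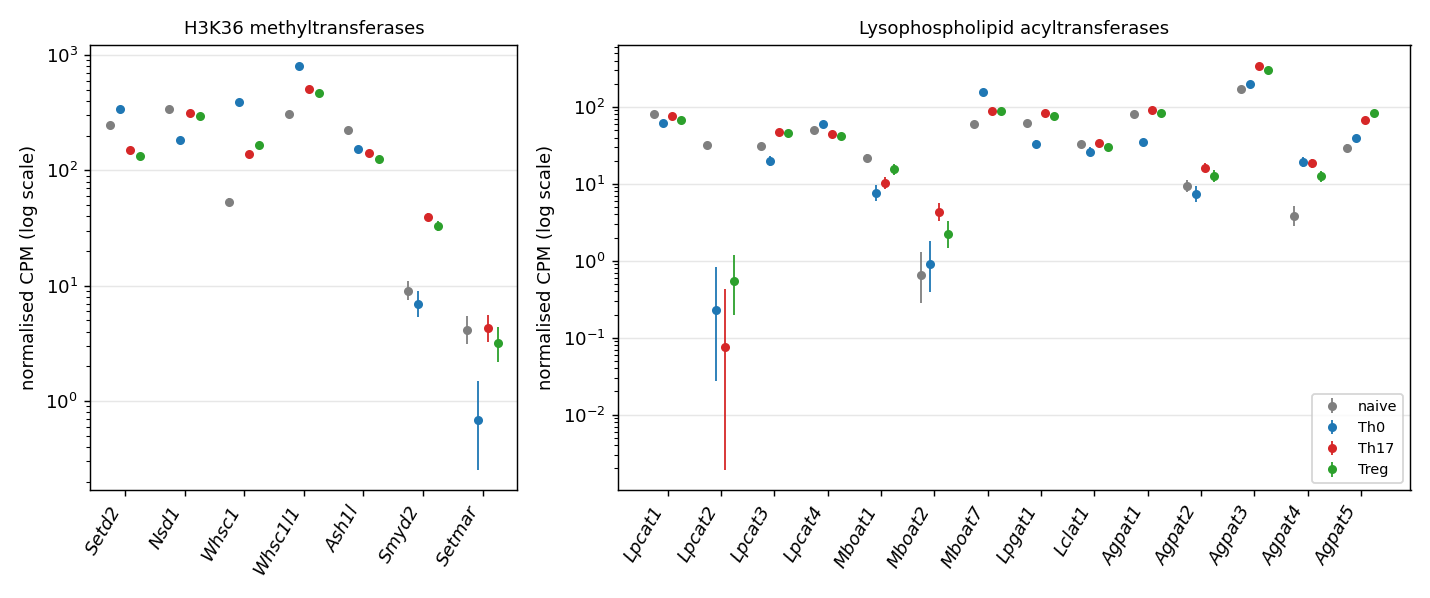
Normalised CPM on a log scale of the H3K36 methyltransferases (left) and lysophospholipid acyltransferases (right), with 1 point per gene and library and 95% Poisson intervals for counting error. Setd2 lay at 341 CPM in Th0 and at 149.6 and 133 CPM in Th17 and Treg, and Lpcat4 lay between 41.7 and 60.6 CPM in the 4 libraries.

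The comparison of Th0 with naive cells asked how the library stimulated for 3 days differed from the naive one. The naive library also held many transcripts of non-T cells. Its level of the Treg gene Foxp3 was above that of the Treg library, at 129 against 51.5 CPM. For every list below, a different mixture of cells and an effect of stimulation therefore could not be told apart. Genes of cell division were higher in Th0, with Top2a, which encodes a topoisomerase of dividing cells, at 115 CPM in naive and 2217 in Th0 (19.3-fold). Enzymes of cholesterol synthesis were higher too, with the HMG-CoA synthase gene Hmgcs1 8.31-fold higher. The list of naive and quiescent T cells lay below the random range, with Klf2, a transcription factor of resting T cells, 19.1-fold lower at 22.9 CPM. Interferon-stimulated and immediate early genes were lower, and so were the markers of other cell types tested. The exceptions were stroma and CD8 T or NK cells, whose lists stayed within the range of random lists.

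In the cell cycle list, 23 of 30 tested members were higher in Th0, 0 were lower and 7 met neither rule, with a median log2 ratio of 2.31 against a central 95% of -0.24 to 0.64 in random lists of matched expression. Bub1 and Kif11, both of the mitotic spindle, were 21.4-fold and 19.7-fold higher, and Cenpe, a kinetochore motor, 18.5-fold. In cholesterol biosynthesis, 17 of 23 members were higher and 0 were lower, with a median of 1.93, and Msmo1 and Fdps were 10.5-fold and 8.35-fold higher. Of the naive T cell and quiescence list, 8 of 18 were lower and 0 higher (median -0.88), including Btg2 (8.73-fold), Klf3 (8.08-fold) and Il6ra (7.60-fold). The T cell activation list had a median of -0.72, with 7 members higher and 5 lower of 17, or 8 lower with library totals. Its members went both ways, as Tnfrsf4 (OX40) and Tnfrsf9 (4-1BB), receptors induced on activated T cells, were 5.47-fold and 5.07-fold higher, while Havcr2 and Egr3 were 20.5-fold and 19.7-fold lower. Among Treg programme genes, 10 of 18 were lower and 3 higher (median -1.28), with Foxp3 93.9-fold, Nrp1 51.2-fold, Gpr83 18.8-fold and Entpd1 8.15-fold lower. The interferon-stimulated list had 17 of 21 members lower (median -2.66), with Oas2 at 77.4 CPM in naive and 0.801 in Th0. The immediate early list had 12 of 13 lower and 1 higher (median -3.06), with Fos at 802 and 5.38 CPM and Fosb at 379.5 and 1.14 CPM.

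The genes furthest apart in Th0 over naive included Tg (192-fold), Psrc1 (93.6-fold), the metallothioneins Mt2 (113-fold) and Mt1 (41.4-fold), Lama5, Tnip3, Sgol2a, Cdc25c and Prr11. Serpinb5 and Ybx2 had 0 counts in naive and were at least 170.5-fold and 118-fold higher. Among the lowest were Csf1r, the receptor for macrophage growth factor, at 771 CPM in naive and 0.801 in Th0, and Vcam1, S100a9, Slc40a1, Ngp, Ltf, Mpeg1, C1qa, C1qc and Sirpa. Itgad and S100a8 had 0 counts in Th0 and were at least 601-fold and 556-fold lower. Of the H3K36 methyltransferases, Whsc1 was 7.34-fold and Whsc1l1 2.59-fold higher, Setmar was 6.06-fold lower and 4 met neither rule. Of the 13 tested acyltransferases, Agpat4 and Mboat7 were higher, Lpcat2 (2 counts in Th0), Mboat1 and Agpat1 were lower and 8 met neither rule, and neither list stood apart (medians -0.33 and -0.33). Th17 programme genes went both ways, with Hif1a 10.5-fold and Il21 7.19-fold higher, Maf 5.58-fold lower and Ccr6 at least 37.1-fold lower.

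Transcripts of other blood cells differed in this comparison as well. All 13 B cell, 11 macrophage, 11 dendritic cell, 9 neutrophil and 10 erythroid and platelet markers tested were lower in Th0. The B cell markers summed to 3971 CPM in naive, 469.7 in Th0, 235 in Th17 and 110.2 in Treg, and the macrophage and monocyte markers to 4005, 45.4, 51.4 and 66.5 CPM. The neutrophil markers summed to 1482 CPM in naive and 1.83 in Th0. Single genes included Igkc at 797 CPM in naive and 39.6 in Th0, Lyz2 at 1112 and 4.92 CPM, Itgax at 175 and 0.572 CPM, and Hbb-bs at 65.0 and 1.03 CPM. Ighd, Fcrla, Ms4a1 and Cr2 of the B cell list were 43.9-fold, 60.4-fold, 25.5-fold and 29.0-fold lower. Cd209a had 0 counts in the 3 cultured libraries. With zeros at 3 counts and no pseudocount, the list medians were -7.82 for macrophages, -5.72 for dendritic cells, -9.12 for neutrophils and -5.74 for erythroid cells and platelets, against -7.37, -4.26, -6.32 and -3.31 on the main scale. The stroma and endothelium list (5 of 6 lower, median -1.47) and the CD8 T and NK cell list (5 of 10 lower, median -1.27) lay within the random range.

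**Figure D3:**
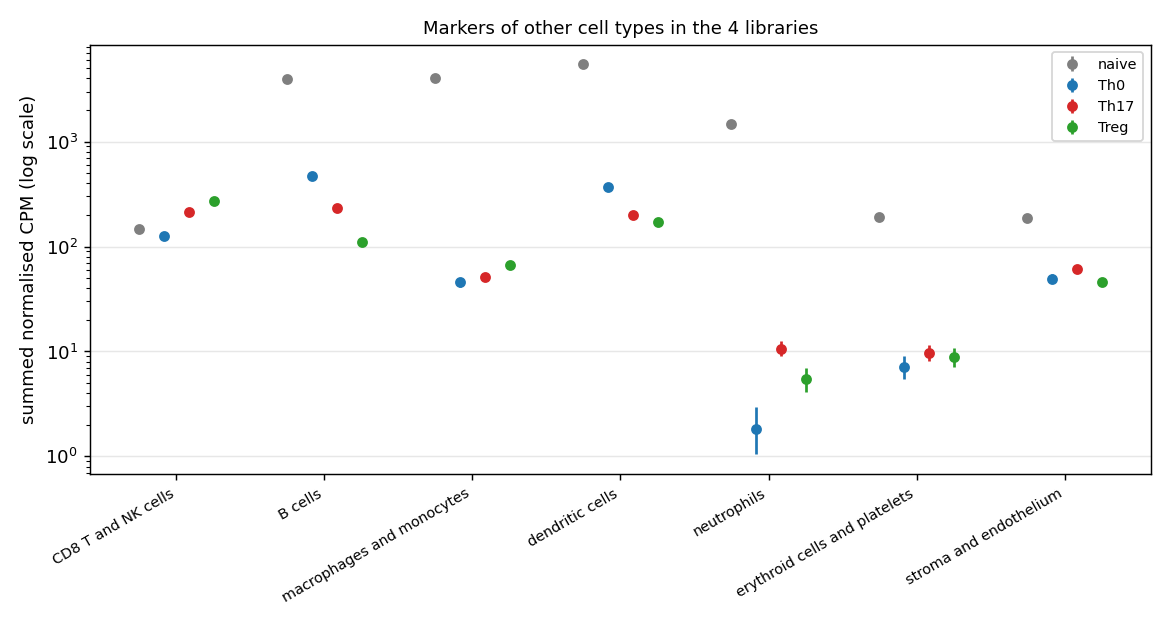
Summed normalised CPM of the markers of 7 other cell types on a log scale, with 1 point per library and 95% Poisson intervals for counting error. The naive library had the highest sum for 6 of the 7 lists, with 4005 CPM for macrophage and monocyte markers against at most 66.5 CPM in the cultured libraries.

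By the size rule, 2590 genes were higher and 3807 lower in Th0 than in naive of 13995 tested, so 40.5% of the calls were higher. With scaling to library totals there were 1884 higher and 4482 lower, or 29.6%. Restricted to genes with at least 10 CPM in Th17 or Treg, an alternative chosen after seeing the data, 2049 were higher and 1640 lower. The balance thus turned to more higher calls. This filter keeps genes present in cultured cells, so it takes out lower calls in particular. Lyz2, Itgad, Itgax, Fdft1 and the haemoglobin genes have a near-identical copy elsewhere, so their counts are uncertain.

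**Figure D4:**
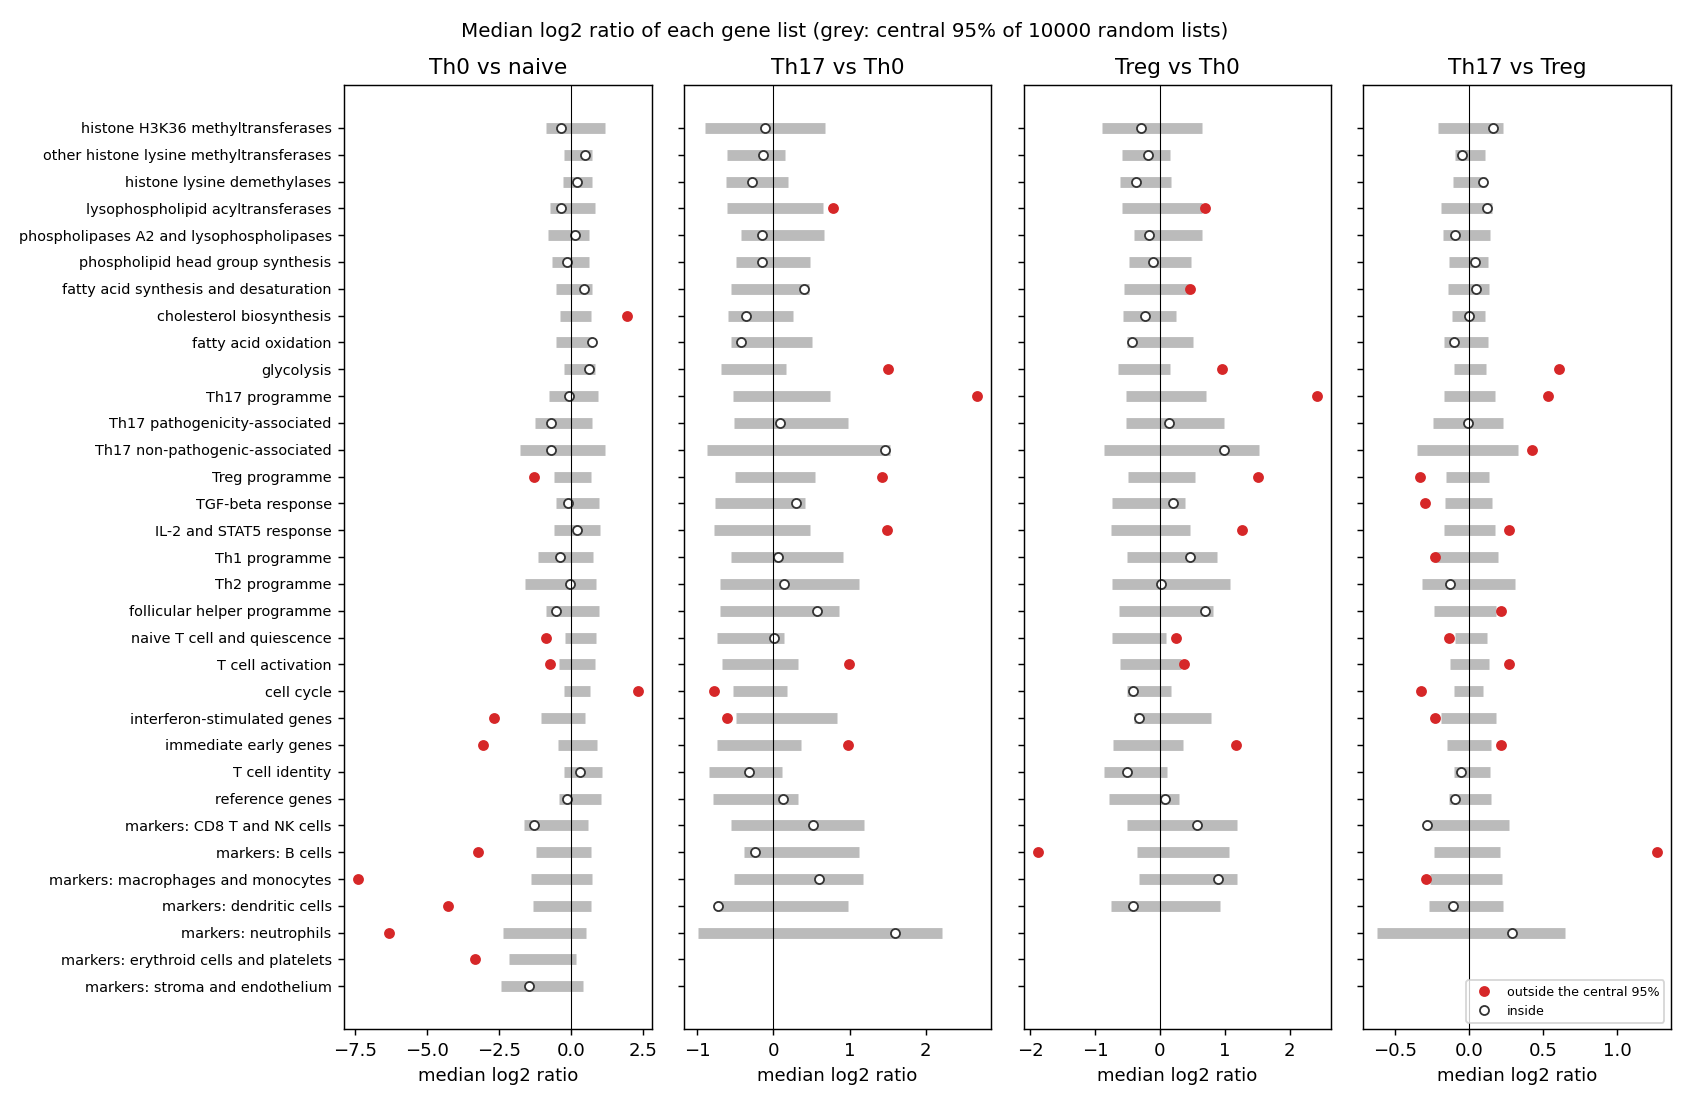
Median log2 ratio of the tested members of each gene list in the 4 comparisons, on an axis of its own for each. Grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside it. The cell cycle list lay at 2.31 for Th0 over naive and at -0.78 for Th17 over Th0.

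The comparison of Th17 with Th0 cells asked how the Th17 culture differed from stimulation alone. Most calls were shared with Treg over Th0, with 2106 genes higher in both, 1272 lower in both and 2 called in opposite directions. Shared calls rest on the same Th0 library, so they cannot be assigned to the Th17 conditions. Il17a had 90.4 CPM in Th17 and 0 counts in Th0, at least 263-fold higher, and Il17f was 257-fold higher. Genes of glycolysis were higher in Th17, with the hexokinase Hk2 at 3.21 CPM in Th0 and 407 in Th17 (127-fold) and the glucose transporter Slc2a1 17.7-fold higher. The cell cycle and interferon-stimulated lists had medians below the random range, although most of their members met neither rule. Hspa1b, an inducible HSP70 chaperone gene, was 85.5-fold lower at 7.16 CPM.

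In the glycolysis list, 15 of 21 members were higher in Th17, 1 was lower and 5 met neither rule (median 1.51), and the phosphofructokinase Pfkl and the lactate transporter Slc16a3 were 18.6-fold higher and at 260.3 against 21.6 CPM. The Th17 programme had 12 of 15 higher and 0 lower (median 2.68, or 3.57 with zeros at 3 counts), with Ccr6 at least 75.7-fold higher. The Treg programme also stood apart, with 12 of 18 higher and 1 lower (median 1.42), and Il2ra, the IL-2 receptor alpha chain, was 9.11-fold, Ikzf4 10.2-fold and Gpr83 10.5-fold higher. Of the IL-2 and STAT5 response, 7 of 10 were higher and 1 lower (median 1.5), among them Lta (21.0-fold), Socs1 (6.54-fold) and Osm (5.76-fold), while Bcl6 was 6.85-fold lower. T cell activation had 8 of 17 higher and 0 lower (median 1.0), with Tnfrsf9 7.05-fold, Egr3 8.92-fold, Egr2 5.20-fold and Slc7a5 3.27-fold higher. Immediate early genes had 6 of 13 higher and 0 lower (median 0.98; 10 higher with library totals), with Egr1 6.57-fold, Junb 5.40-fold, Ier2 5.37-fold and Fosl2 3.88-fold higher. Of the lysophospholipid acyltransferases, 5 of 13 were higher and 0 lower (median 0.78): Agpat1 by 2.65-fold, Lpgat1 by 2.49-fold, Lpcat3 by 2.35-fold, Mboat2 by 4.74-fold and Agpat2, at 16.2 against 7.44 CPM and called under 3 of 4 scalings. In the cell cycle list, 12 of 30 were lower and 0 higher (median -0.78), with Bub1 4.04-fold, Kif11 3.15-fold, Top2a 2.74-fold and Ccna2 2.57-fold lower. With library totals 4 were lower (median -0.47), and with upper quartile scaling 8 (median -0.63). The interferon-stimulated list had 3 of 14 lower and 11 meeting neither rule (median -0.61, or 1 lower and -0.32 with library totals), namely Rsad2 (28.9-fold), Oas1a (3.35-fold) and Bst2 (2.03-fold), of which Oas1a was called under 3 and Bst2 under 2 of the 4 scalings, and Usp18 met neither rule at a log2 ratio of -0.92.

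Among H3K36 methyltransferases, Smyd2 (5.66-fold) and Setmar (6.21-fold) were higher in Th17, Setd2 and Whsc1 (2.82-fold) were lower, and 3 met neither rule. The list median was -0.11, and it was 0.21 with library totals and 0.04 with upper quartile scaling. The naive and quiescence list did not stand apart (median 0.01), though Igfbp4 (7.33-fold), Il6ra (6.20-fold) and Btg2 (3.34-fold) were higher and Tcf7 3.04-fold lower. The genes furthest above Th0 also included Itga7 (266-fold), Tgm2 (93.5-fold), Cysltr1 (174-fold), Scrt1 (123-fold), Gipr (117-fold), Egln3 (47.4-fold), Myof (80.8-fold) and Crispld2, whose Th0 level rested on 3 counts. Those furthest below were Gbp10 (209.9-fold), Hspa1a (60.1-fold), Hspa1l (75.5-fold), Rasgef1a, Hspb1, Mt2 (16.6-fold), Ifi203, Gbp6, Cldn10 and Mndal. The symbol Gbp6 stood on more than 1 gene identifier, at 15.5-fold and 12.7-fold lower.

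By the size rule, 2683 genes were higher and 1649 lower in Th17 than in Th0 of 13324 tested, so 61.9% of the calls were higher. That share was 79.3% with library totals (3528 higher, 922 lower) and 71.2% with upper quartile scaling (3075 and 1244). Hspa1a, Hspa1b, Hspb1, Gbp10, Ifi203, Oas1a, Socs2 and a Gbp6 identifier have near-identical copies elsewhere, so their counts are uncertain.

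The comparison of Treg with Th0 cells asked the same question for the Treg culture. It used the same Th0 library, so calls shared with Th17 over Th0 cannot be assigned to the Treg conditions. Foxp3 had 51.5 CPM in Treg and 1.37 in Th0, 37.5-fold higher. Th17 genes were also higher in Treg, with Il17f 87.2-fold and Il17a at least 42.8-fold above Th0. Scd1, which encodes a fatty acid desaturase, was 6.65-fold higher at 291 CPM. Markers of B cells were lower in Treg than in Th0.

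The Treg programme had 12 of 18 members higher and 1 lower (median 1.51), with Socs2 16.0-fold, Ikzf4 12.8-fold and Gpr83 15.3-fold higher. The Th17 programme had 10 of 14 higher and 0 lower (median 2.42), with Ccr6 at least 97.2-fold higher. Glycolysis had 10 of 21 higher and 1 lower (median 0.96), with Hk2 60.6-fold, Pfkl 11.6-fold, Slc16a3 6.93-fold and Slc2a1 6.49-fold higher. The IL-2 and STAT5 response had 5 of 10 higher and 1 lower (median 1.27), with Lta 19.9-fold, Socs1 5.31-fold and Osm 4.84-fold higher and Bcl6 11.4-fold lower. Immediate early genes had 7 of 13 higher and 1 lower (median 1.18), led by Egr1 (4.75-fold), Ier2 (4.61-fold), Junb (3.90-fold) and Jund (3.91-fold). Fatty acid synthesis and desaturation had 6 of 18 higher and 1 lower (median 0.46), with Acsl1 3.96-fold and Elovl6 2.97-fold higher and Acsl6 at least 8.67-fold. Its place rested at the edge of the range, at percentile 97.75. For Th17 over Th0 this list had 7 of 19 higher and 1 lower (median 0.40, percentile 95.9). For Th17 over Treg its median was 0.05, so the result was not particular to Treg. The acyltransferases had 4 of 13 higher and 0 lower (median 0.70): Agpat1 (2.43-fold), Lpgat1 (2.29-fold), Lpcat3 (2.29-fold) and Agpat5 (2.12-fold, called under 3 of 4 scalings). T cell activation had 4 of 17 higher and 1 lower (median 0.38; 7 higher with library totals and 2 with DESeq2 size factors), with Egr3 at 18.8 against 1.72 CPM, Tnfrsf9 6.43-fold and Cd44 2.06-fold higher and Slc3a2 2.17-fold lower, the last called under 2 of 4 scalings and Cd44 under 3. The naive and quiescence list had 6 of 18 higher and 2 lower (median 0.25), with Igfbp4 7.93-fold, Il6ra 4.30-fold, Btg2 3.71-fold and Klf2 3.26-fold higher. Of the B cell markers, 11 of 12 were lower (median -1.89), including Igkc (16.9-fold), Ms4a1 (9.52-fold) and Cd79a (4.70-fold). Setd2 and Whsc1 (2.36-fold, called under 3 of 4 scalings) were lower and Smyd2 (4.73-fold) and Setmar (3.16 against 0.687 CPM) higher among the H3K36 methyltransferases, whose median was -0.30 and, with library totals, 0.05.

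Myof (145-fold), Tgm2 (62.4-fold), Ermn (37.9-fold), Cysltr1 (62.8-fold), S1pr3 (84.7-fold), Syt13 (64.9-fold), Itga7 (62.4-fold), Crispld2 (3 counts in Th0) and Lif, a cytokine of the IL-6 family (29.2-fold), completed the genes furthest above Th0. Hspa1b (339-fold), Hspa1a (162-fold), Hspa1l (303-fold, at 0.361 CPM in Treg), Gbp10 (284-fold), Serpinb5 (92.7-fold, 5 counts in Treg), Mt2 (28.4-fold), Mt1, Gbp6 and Rasgef1a were furthest below it. So were Hspb1 with 1 count and Cldn10 with 2 counts in Treg. Gbp10, Hspa1a, Hspa1b, Hspb1, Elovl6 and Socs2 have near-identical copies elsewhere, so their counts are uncertain. By the size rule, 2653 genes were higher and 1575 lower of 13138 tested, so 62.7% of the calls were higher, against 81.8% with library totals (3629 and 810) and 72.5% with upper quartile scaling (3063 and 1160).

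The comparison of Th17 with Treg cells asked how the polarised cultures differed from each other. By the size rule 255 genes were higher and 165 lower in Th17 of 13346 tested, and the 420 calls became 648 with a pseudocount of 0.5 CPM, 180 with 4 CPM (113 higher, 67 lower) and 202 with the authors' FPKM (113 higher, 89 lower). Among cytokine genes, Il22 was higher in Th17 at 28.3 against 3.34 CPM, as were Il17a 6.15-fold, Il21 3.29-fold and Il17f 2.95-fold above Treg. Foxp3 was 4.57-fold lower in Th17, and the TGF-beta receptor gene Tgfbr2 2.32-fold lower. Slc2a3 and Slc2a1, which encode glucose transporters, had 611 and 327 CPM in Th17 against 168 and 120.3 CPM in Treg.

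Scrt1 stood furthest apart, with 155 CPM in Th17 and 3 counts in Treg (log2 interval 7.61 to 11.44). Gipr (10.7-fold), Serpinb5 (29.4-fold, 5 counts in Treg), Ptpn5, Selp, Serpinf1, Cd93, Ero1l (4.58-fold), Pax5 (5.53-fold) and Lilrb4a (4.39-fold) followed. Ube2l3, with 4 genes elsewhere carrying a near-identical copy, was 8.94-fold lower in Th17, and others lower were Pla2g4f, Zfp292 (4.89-fold), Pkhd1l1, Phc3 (4.44-fold), Atp1b1, Usp49, Gpr146, Trex1 and Zbtb42. The Th17 programme had 6 of 15 higher and 0 lower (median 0.54, or 0.94 with zeros at 3 counts). Glycolysis had 3 of 21 higher and 0 lower (median 0.61), with Hk2 2.10-fold higher, and Pdk1 met neither rule. Of the Treg programme 4 of 18 were lower (median -0.33), with Nrp1 3.10-fold, Itgae 2.59-fold and Socs2 2.11-fold lower. In the TGF-beta response 1 of 11 was lower (median -0.30), while Ldlrad4, Tgfbr1 and Pmepa1 had log2 ratios of -0.94, -0.76 and -0.58. In the cell cycle list 0 of 30 met the rule, and the median was -0.32 against a random range of -0.10 to 0.09, with Cdc6 at -0.65 and Mcm5 at -0.62.

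The Th1 programme had 2 of 10 lower (median -0.23, or -0.33 with zeros at 3 counts), Fasl (2.61-fold) and Nkg7 (2.48-fold), and its place rested at the edge of the range, at percentile 2.47. Of the interferon-stimulated genes, 2 of 15 were lower (median -0.23, or -0.35 with zeros at 3 counts), Ifit1 with 3 counts in Th17 (log2 interval -6.28 to -2.29) and Ifit3 (6.86-fold). In naive and quiescence 1 of 18 was lower (median -0.13), Txnip at 2.78-fold. T cell activation had 2 of 17 higher (median 0.28), Egr2 (3.83-fold) and Nfil3 (2.16-fold). Medians were 0.27 for the IL-2 and STAT5 response, where Il2 was 3.10-fold lower, 0.22 for immediate early genes and 0.22 for the follicular helper programme, where no gene met the rule. The list associated with non-pathogenic Th17 cells had a median of 0.43, and its member with the call, Cd5l, was 3.20-fold lower. Of the B cell markers, 9 of 13 were higher in Th17 and 0 lower (median 1.27, or 1.97 with zeros at 3 counts), with Ebf1 5.12-fold, Blk 4.79-fold and Cd79a 3.91-fold higher. Of the macrophage and monocyte markers, 2 of 11 were lower (median -0.29), C1qa with 3 counts in Th17 (log2 interval -5.37 to -1.23) and Lyz2 (2.44-fold). Il22, Ifit3, Lyz2, Socs2 and Ube2l3 have near-identical copies elsewhere, so their counts are uncertain. None of the 7 H3K36 methyltransferases or 13 tested acyltransferases met the rule in this comparison, with medians of 0.17 and 0.12 within the random range.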

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

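The tests of blood cell markers, of the scaling of the naive library, of heat shock genes and of mixed material were chosen only after the results were seen. The tests of receptor genes, of GC content and gene length, of depth and of the Treg scaling were set before.

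Pax5 and Zfp292 were called in opposite directions in Th17 and Treg against the shared Th0 library. Pax5, a B cell transcription factor, had a log2 ratio of 1.16 for Th17 over Th0 and -1.01 for Treg over Th0, the latter called under only 2 of 4 scalings. Zfp292 had -1.19 for Th17 over Th0 and 1.07 for Treg over Th0, each called under 3 of 4 scalings. For Th17 over Treg, called under 4 of 4 scalings, Pax5 had a log2 ratio of 2.18 (interval 1.98 to 2.99) and Zfp292 -2.26 (interval -2.44 to -2.14), which compares the reads of these libraries and, without replicates, does not test the conditions. As a list the B cell markers, Pax5 among them, had 9 of 13 members higher in Th17 than in Treg and 11 of 12 lower in Treg than in Th0, but in Th17 over Th0 1 was higher and 5 were lower (median -0.25, or 0.05 with library totals).

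The naive library held transcripts of non-T cells at levels far above the cultured libraries. Genomic DNA or other non-specific reads are argued against by olfactory and vomeronasal receptor genes, whose summed CPM in naive was 0.812 of that in the highest cultured library (interval 0.590 to 1.12). The sum was 6.37 CPM in naive, 7.09 in Th17 and 7.85 in Treg. In Th0 it was lower, at 2.52 CPM (22 counts against 78 in naive), so against Th0 alone the receptor genes do not argue this. A scaling error of the naive library is argued against as well, because it would move all genes alike. The lowest median log2 ratio of all tested genes over 4 scalings was -0.38, while the macrophage list lay at -7.37. Most of these scalings centre the bulk of genes by design, so only the gap between list and median bears on this. RNA of other blood cells remains open: that 12 of 12 abundant markers of B cells, macrophages, neutrophils and red cells were at least 4-fold higher in naive than in every cultured library, the smallest difference being 6.55-fold for Ighm, restates the observation and does not test it. Such RNA may come from cells left by the CD4 selection, and how much of the lower calls of Th0 it accounts for was not measured.

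Th0 differed from Th17 and Treg in about 10 times as many genes as these differed from each other, at 4332, 4228 and 420 calls. Trends with GC content and gene length are argued against as the whole cause, since 83.4% of the Th17 calls against Th0 were kept when both were removed. Depth is argued against too, as Th0 and Treg had nearly the same total count (10272122 and 10256627). With all libraries thinned to the shallowest, the Th17 calls against Th0 were 10.1 times those against Treg. The totals were too close for thinning to change this much, so it adds little. A stress response of the Th0 culture or its handling stays open: 10 of 10 heat shock genes, a set chosen after some of them were seen to differ and so no test of it, were at least 2-fold higher in Th0 than in both, from 2.02-fold for Hspa8 to 85.5-fold for Hspa1b over Th17. Against naive the set was mixed. Th0 over naive was 0.740 for Hsph1, 1.14 for Hspa8 and 1.74 for Hspd1, and from 2.01 (Dnajb1) to 62.4 (Hspb1) for the rest. The culture conditions also stay open and untested, and with 1 library each they are confounded with handling.

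The Treg library carried the Th17 cytokine transcripts Il17a and Il17f. Over the 498 genes at least 4-fold higher in Th17 than Th0 and with at least 10 CPM in Th17, the median Treg level was 82.0% of the Th17 level, with Il17f at 33.9% and Il17a at 16.3%. These genes were chosen only by their ratio to Th0 and are not a set of Th17 genes. Their median share restates that the Th17 and Treg libraries were close (Spearman rho 0.974 across genes). Th17 material mixed into the Treg library is argued against as the whole source of Il17f. Of these 498 genes, 15, the far tail of the set, had an upper limit of the Treg to Th17 ratio below the lower limit for Il17f (30.4%), and Scrt1 allowed a share of at most 0.511% and Gipr, the next gene, 11.1%. The choice among the 4 scalings does not account for Il17f, whose lowest log2 ratio for Treg over Th0 was 4.77. These scalings moved the median of all tested genes by at most 0.31 from TMM, so they could hardly have removed it. The tests of mixing and scaling were made for Il17f and not for Il17a. For Il17a the lower limit was 13.7%, and only Scrt1 and Gipr had upper limits below it, so mixing stays open for Il17a. Expression of Il17a and Il17f under the Treg conditions may be biological, as a hypothesis found and examined on the same data.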

How the results depend on the processing

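The alternatives with GC content and gene length, T cell identity genes, expressed genes or another library in place of a compared one were chosen after seeing the data. No called list median or named gene changed its direction under the alternatives run for it. The number of lists that stood apart stayed within 1.5 times in all comparisons: 12 to 13, 9 to 10, 10 and 13 to 16. Another scaling shifts a list and its random lists almost alike. The scaling alternatives could therefore hardly change this number, and only those of pseudocount, count filter and unit bear on it. Of the counts of genes, 119 values stayed within 1.5 times and 28 did not. With a pseudocount of 4 CPM, lower calls of Th0 over naive numbered 2534, Th17 over Th0 had 2863 calls (1618 higher), Treg over Th0 2681 (1503 higher) and Th17 over Treg 180 (113 higher, 67 lower). With 0.5 CPM, Th17 over Treg had 648 calls (286 lower). Low genes cross the 2-fold line with the pseudocount by construction. With the authors' FPKM, Th0 over naive had 1458 higher, Th17 over Th0 2868 calls (681 lower), Treg over Th0 2760 (597 lower) and Th17 over Treg 202 (113 higher, 89 lower). With library totals, lower calls were 922 for Th17 and 810 for Treg over Th0. Scaled to T cell identity genes, Th17 over Th0 had 943 lower, and Treg over Th0 had 4422 higher and 640 lower. With naive in place of Th0, lower calls were 2565 for Th17 and 2425 for Treg. Of the main calls, 1270 of 4332 for Th17 and 1118 of 4228 for Treg were shared with that setting. A count within 1.5 times therefore need not mean the same genes. For Th0 over naive, genes with at least 10 CPM in Th17 or Treg gave 3689 calls (2049 higher, 1640 lower). The Treg library in place of Th0 gave 2425 lower. Beyond the changes that follow from the construction, the cause was not tested. Of the list medians 702 values stayed within the reach of the counting interval (of the members' median width) and 171 moved further, and of the named gene values 2046 and 502. Depth limits genes of a few counts, such as Il17f in Th0 with 4 counts.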

Other observations

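The genes named here were chosen after their values were seen, and no hypothesis was tested on them.

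The glycerophosphocholine phosphodiesterase gene Gpcpd1 had 263 CPM in Th0, 41.8 in Th17 and 44.6 in Treg. The gene Pcyt1a, of phosphatidylcholine synthesis, had 57.4 CPM in Th0, 24.8 in Th17 and 22.9 in Treg, and was called lower under 3 of 4 scalings in both Th17 and Treg against Th0. Fasn, the fatty acid synthase gene, was higher in both than in Th0, with 219.8 CPM in Th0, 547 in Th17 and 491 in Treg. Ezh2, an H3K27 methyltransferase, had 50.8 CPM in naive, 327 in Th0, 62.1 in Th17 and 77.2 in Treg. Among the lists that stayed within the random range in Th17 over Th0 were phospholipases A2 and lysophospholipases (median -0.16, or 0.15 with library totals), phospholipid head group synthesis (median -0.15, or 0.11), cholesterol biosynthesis (median -0.36, or -0.05) and T cell identity genes (median -0.32, or -0.01).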
